A study of Mus musculus with 10 samples.

How the data were processed

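RNA was sequenced from mouse CD8+ T cells in 10 libraries that fall into 6 groups. Per the labels' protocols, the cells came from spleens of 6-week-old female C57Bl/6 mice that were wild type (WT) or Ikaros-Zn4-/-, that is, homozygous for a deletion affecting zinc finger 4 of the DNA-binding domain of Ikaros. CD8+ cells of naive surface phenotype, with low or absent CD44, were sorted after negative enrichment and either used directly (0 min) or kept on plates coated with antibodies to CD3 and CD28, which engage the T cell receptor (TCR) and its costimulatory receptor, for 30 or 120 min. Per the labels' protocols, total RNA was made into single-end libraries with the TruSeq RNA kit v2, a kit that does not mark strand, and sequenced on a HiSeq. Each genotype has 2 libraries at 0 min, 2 at 30 min and 1 at 120 min.

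The authors deposited a table of RPKM values (reads scaled to transcript length and library size), with 1 column per library and 1 row per gene. Per the submitters' processing notes, the tools were TopHat2 2.0.12, TopHat and HTSeq 0.6.1, with the genome builds mm10 and GRCm38. Their roles, the annotation version, the gene lengths behind the RPKM values and the filter on genes are not given in the sources used here. The deposited table holds 12637 genes, and every gene in it reaches a mean of at least 1 RPKM in at least 1 of the 6 groups, so genes with low expression in every group cannot be examined. Of the gene identifiers, 12567 were found in GENCODE M21 (GRCm38), which gave coordinates and exon lengths, and 70 were not. In the table, 9809 genes were annotated as protein coding, 7 symbols occurred more than 1 time and 15 carried an asterisk. Because the kit does not mark strand and the counting options are not recorded, reads of genes that overlap on opposite strands cannot be told apart, and the values of near-identical paralogs such as members of the Oas and immunoglobulin families are uncertain.

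Depth was recovered from the deposited RPKM values, since a read count divided by a gene's length and by the library's total takes evenly spaced steps. With the union exon lengths of GENCODE M21, 65.7% to 71.1% of the values below 200 reads fell within 0.01 read of a whole number, against 2% by chance. The depths found were 4.50 to 13.3 M reads per library, and the recovered reads of the table sum to 94.0% to 101% of them. A sum above the depth cannot be right, so the depths or lengths are slightly off at least in the 5 libraries where it occurs. In the shallowest library 1 read on a 1 kb transcript corresponds to 0.222 RPKM, and in the deepest to 0.075 RPKM. Across genes, which are not independent replicates, Pearson's r of the log2 values between the 2 libraries of a group was 0.959 to 0.971. The chi-square of the recovered reads between such libraries was averaged over the 8821 to 9278 better-counted genes of each pair. It was 14.2 to 21.4 per gene, where counting error alone gives about 1. On average over these genes counting error is thus not the main part of the spread, but genes with fewer reads were not covered.

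The tests were run in R 4.3.3 with limma 3.58.1 on log2(RPKM + 1) of the 12203 genes with a mean of at least 0.5 RPKM over the 10 libraries. Log2 changes and 2-fold counts on this scale refer to RPKM + 1. For genes of low RPKM they understate the fold change of RPKM itself. A linear model with 1 mean per group (4 residual degrees of freedom) was fitted to all 10 libraries, because no group has more than 2 libraries, and moderated with an intensity trend. The 120 min groups hold 1 library each, which was assumed to vary like the other groups. The stimulation contrasts compared 30 or 120 min with 0 min in each genotype and as the mean of both genotypes, and the genotype contrasts compared Ikaros-Zn4-/- with WT cells at 0 and at 30 min. The genotype difference over all times came from an additive model of genotype and time (6 residual degrees of freedom). The interaction contrasts compared the responses of the genotypes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and all tests were two-sided. At 120 min the genotypes were compared as a difference of 1 library against 1, with no test. Depth tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

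The design, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. From 26 gene lists, the 23 with at least 3 measured members were tested with limma's camera, which asks whether a list is shifted against the other genes, with a preset correlation between genes of 0.01 and adjustment over the lists of a contrast. The lists were immediate early genes, MAP kinase feedback regulators, NF-kB pathway genes, activation transcription factors, TCR proximal signalling, negative regulators of TCR signalling, cytokines and chemokines, activation surface receptors, naive and quiescence genes, effector and memory genes, the Ikaros family, Notch pathway genes, ribosome biogenesis and MYC targets, glycolysis and nutrient transport, the type I interferon response, heat shock and stress, proliferation, apoptosis regulators, chromatin remodelling and Ikaros partners, B cell, myeloid, CD4 and regulatory T cell, natural killer cell, and erythroid and platelet markers, reference genes and mitochondrial mRNAs. Some genes stand in more than 1 list. Named genes were the Ikaros family and up to 4 members per list with the smallest adjusted p. The 10 largest rises and 10 largest falls among called genes were also named. The rule also asked that their libraries not overlap between the groups, but this was not applied gene by gene, so overlap is possible. Where no member of a list passed, the 1 or 2 with the highest expression were taken. For the interactions the 5 largest differences of each sign among genes called in either genotype were named, and at 120 min the 10 largest genotype differences of each sign among genes with a mean of at least 2 RPKM. Short RNA and receptor segment models named by the rule were left out of the text where their values rest on few reads.

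Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at a mean of 2 RPKM, quantile normalization, scaling by the median ratio, a spread from the compared groups only, moderation without the trend, the replicate number as a block, and leaving out each library in turn. For the lists, a correlation estimated per list and limma's fry, which tests whether a list's genes move one way without comparing them with other genes, were also run. The fits were tested on simulated data of 12140 genes of which 200 were changed. Genes were drawn independently, each with the median replicate spread at its expression level. Library effects shared by genes were thus absent, so the shares below may not carry over to the real contrasts. In the simulation of the genotype contrast over all times 92.4% of 4-fold, 76.1% of 2-fold and 37.3% of 1.5-fold changes were recovered, with 7 false calls among 144. For 30 min over both genotypes these shares were 92.4%, 65.7% and 26.9%, with 7 false calls among 130. For the 30 min interaction they were 50%, 0% and 0%, with 4 false calls among 37 (10.8%), and for the genotype at 0 min 5 of 64 calls were false (7.81%).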

Results

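Gene expression was measured in naive splenic CD8+ T cells of WT and Ikaros-Zn4-/- mice before and after stimulation through CD3 and CD28. Ikaros is a zinc finger transcription factor of lymphocytes, and in the mutant the protein lacks zinc finger 4, which contributes to the choice of DNA sites. The series asks how Ikaros regulates the genes that TCR signalling induces. For WT cells there were 2 libraries at 0 min (10.7 and 8.89 M reads), 2 at 30 min (11.6 and 5.82 M) and 1 at 120 min (10.5 M). For Ikaros-Zn4-/- cells there were 2 at 0 min (13.3 and 4.50 M), 2 at 30 min (10.2 and 5.77 M) and 1 at 120 min (9.20 M). The labels do not say that replicates are separate mice, so p-values measure only the spread between these samples.

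Ikzf1, the gene that encodes Ikaros (chromosome 11, 11685003 to 11772926, GRCm38, GENCODE M21, as for all positions here), was expressed in every library. In WT cells its level was 134 and 148 RPKM at 0 min, 156 and 171 RPKM at 30 min and 150 RPKM at 120 min. In Ikaros-Zn4-/- cells it was 206 and 226 RPKM at 0 min, 240 and 263 RPKM at 30 min and 214 RPKM at 120 min. All 5 mutant libraries lay above all 5 WT libraries, with a log2 difference over all times of 0.59 (SE 0.08, limma, adjusted p = 0.00165). A value per gene does not resolve the exon that was deleted, so these levels do not check the deletion itself. At 0 min alone the Ikzf1 difference was 0.61 (adjusted p = 0.0847) and at 30 min 0.62 (adjusted p = 0.0748), neither past the threshold.

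What stimulation changed within 30 min was examined over both genotypes, 4 libraries against 4. Fosl2, a subunit of the AP-1 transcription factor (chromosome 5, 32135801 to 32157842), went from 7.18 ± 2.27 to 146 ± 24.9 RPKM in WT cells and from 6.83 ± 1.13 to 78.6 ± 42.0 RPKM in mutant cells (SD, n = 2 libraries per group). Tnf, the cytokine tumour necrosis factor (chromosome 17, 35199381 to 35202007), went from 6.36 ± 0.163 to 59.4 ± 1.43 RPKM in WT and from 9.79 ± 0.712 to 88.0 ± 28.1 RPKM in mutant cells. The falls were smaller, among them Art2b, an ADP-ribosyltransferase of the T cell surface, and the interferon-induced gene Ifit1. The median log2 change of all genes was -0.13 at 30 min and -0.32 at 120 min, and all stimulation changes of genes below are given relative to the median of their contrast, while the tests and counts were made on the deposited scale. An adjusted p thus tests the deposited change and not the value printed beside it. For Ikzf3 at 30 min these are -0.308 and -0.175, and for Ikzf1 at 120 min 0.039 and 0.355.

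At 30 min, 22 of 28 immediate early genes rose and 0 fell (23 and 0 adjusted over the list alone). Maff, a small Maf protein, rose by 4.19 on the log2 scale (SE 0.41, adjusted p = 0.00258), Fosl2 by 3.85 (SE 0.26, adjusted p = 0.000872), Gadd45b, a stress-inducible growth arrest gene, by 2.80 (SE 0.16, adjusted p = 0.000506) and Klf10, a zinc finger repressor, by 2.19 (SE 0.08, adjusted p = 0.00015). The list was shifted upward with camera (adjusted p = 2.87e-20; adjusted p = 0.158 with an estimated correlation). Among MAP kinase feedback regulators 8 of 12 rose and 0 fell (11 and 0 adjusted over the list alone). These include the MAP kinase phosphatases Dusp5 at 3.59 (SE 0.26, adjusted p = 0.00103) and Dusp4 at 3.20 (SE 0.29, adjusted p = 0.00212). The call of this list held under both correlations, with camera adjusted p = 5.88e-11 and adjusted p = 0.0435 with an estimated correlation. In the NF-kB list 8 of 16 rose and 0 fell (9 and 0 adjusted over the list alone), including the inhibitors Nfkbia at 1.97 (SE 0.10, adjusted p = 0.000438) and Tnfaip3 at 2.28 (SE 0.29, adjusted p = 0.00593), with a camera adjusted p = 3.14e-06 and adjusted p = 0.158 with an estimated correlation. Outside the gene lists, Errfi1, an inhibitor of the epidermal growth factor receptor, rose by 3.38 (SE 0.15, adjusted p = 0.000208) and Irs2, an insulin receptor substrate, by 3.35 (SE 0.33, adjusted p = 0.00258).

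Activation transcription factors rose for 6 of 17 members and fell for 0 (8 and 1 adjusted over the list alone). Examples were Nfil3 at 2.86, Crem at 2.19 and Egr2 at 1.80. Camera gave this list an adjusted p = 0.00045, and adjusted p = 0.253 with an estimated correlation. Of 14 cytokine and chemokine genes 4 rose and 0 fell (4 and 1 adjusted over the list alone), Tnf by 3.15 and Tnfsf11, which encodes RANKL, by 1.70. Their camera adjusted p = 0.0204 became adjusted p = 0.344 with an estimated correlation and 0.0683 after quantile normalization. Of 15 activation surface receptors 6 rose and 1 fell (the same numbers adjusted over the list alone). Among them were Cd69, an early activation marker, at 1.83, Tfrc, the transferrin receptor, at 1.24 and Icos, a costimulatory receptor, at 1.15. For the list, camera gave adjusted p = 0.00997 and adjusted p = 0.171 with an estimated correlation. Glycolysis and nutrient transport genes rose for 4 of 16 members and fell for 0 (5 and 0 adjusted over the list alone), all 4 encoding membrane transport proteins, among them the amino acid transporter Slc38a2 at 2.35 and the glucose transporter Slc2a1 at 1.94. The camera adjusted p = 0.00275 for the list became adjusted p = 0.158 with an estimated correlation. Heat shock and stress genes rose for 4 of 13 members and fell for 0 (5 and 0 adjusted over the list alone). The chaperone Hspa5 of the endoplasmic reticulum rose by 1.49, Ddit3 by 1.81 and Atf4, both transcription factors of the integrated stress response, by 1.26. That list had a camera adjusted p = 0.000349, an adjusted p = 0.399 with an estimated correlation and an adjusted p = 0.0745 with fry.

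Naive and quiescence genes rose for 5 of 20 members and fell for 1 (5 and 4 adjusted over the list alone). These include the lymph node homing receptor Ccr7 at 1.75, the antiproliferative gene Tob1 at 2.25 and Btg1 at 0.92. Their camera adjusted p = 0.0319 became adjusted p = 0.279 with an estimated correlation and 0.467 after quantile normalization. Notch pathway genes rose for 2 of 8 members and fell for 0 (4 and 0 adjusted over the list alone). The Notch target Hes1 rose by 1.08 (1.61 in mutant cells alone, while no Notch pathway gene was called in WT cells alone). As a list they had camera adjusted p = 0.026 and adjusted p = 0.375 with an estimated correlation. In the type I interferon list 0 of 24 rose and 9 fell (0 and 11 adjusted over the list alone). Among them were Ifit1 at -1.03 (SE 0.15, adjusted p = 0.00498) and Zbp1, a sensor of nucleic acids, at -0.34 (adjusted p = 0.0124, and 0.0543 without WT 0 min replicate 2). That list had a camera adjusted p = 0.0319 and adjusted p = 0.72 with an estimated correlation.

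Other lists were not called at 30 min. TCR proximal signalling genes were split, 3 of 22 up and 3 down (3 and 6 adjusted over the list alone, camera adjusted p = 0.889). These include the costimulatory receptor Cd28 at 2.38, the adaptor Bcl10 at 0.98 and the TCR subunit Cd3e at -0.60 (adjusted p = 0.0115, and 0.052 without WT 0 min replicate 2). Negative regulators of TCR signalling were 2 of 23 up and 2 down (3 and 3 adjusted over the list alone, camera adjusted p = 0.789). Examples were the adaptor Sla2 at -0.76 and the phosphatase family member Ubash3a at -0.37. Effector and memory genes were 1 of 18 up and 5 down (2 and 6 adjusted over the list alone, camera adjusted p = 0.889). The chemokine receptor Cxcr3 fell, at -0.91. Ribosome biogenesis genes were 4 of 24 up and 1 down (6 and 5 adjusted over the list alone, camera adjusted p = 0.246). These include the nucleolar proteins Nop56 at 0.91 and Gnl3 at 0.78. Proliferation genes were 1 of 17 up and 2 down (1 and 3 adjusted over the list alone, camera adjusted p = 0.971). Examples were the replication clamp Pcna at 1.18 and the cyclin Ccnd2 at -0.80. Apoptosis regulators were 3 of 13 up and 2 down (3 and 2 adjusted over the list alone, camera adjusted p = 0.34). The death-promoting gene Pmaip1 rose by 1.40. Of 17 chromatin remodelling genes 0 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.805, and 0 of either sign after scaling by the median ratio). In the Ikaros family Ikzf5 had a change of 0.51 (adjusted p = 0.0433) and Ikzf3 of -0.17 (adjusted p = 0.0382; camera adjusted p = 0.889 for the list), and leaving out any of the 0 or 30 min libraries ended both calls, with adjusted p from 0.0525 to 0.121 for Ikzf3 and from 0.0542 to 0.121 for Ikzf5. The Ikzf3 call was also lost after quantile normalization (adjusted p = 0.0683) and after scaling by the median ratio (adjusted p = 0.213).

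Of 5 B cell markers 1 rose and 1 fell at 30 min (2 and 2 adjusted over the list alone, camera adjusted p = 0.656). The lower gene was Cd79b, a chain of the B cell receptor, at -0.78. None of 3 myeloid markers passed (0 adjusted over the list alone, camera adjusted p = 0.889, Cst3 at 0.00) and none of 7 mitochondrial mRNAs (0 adjusted over the list alone, camera adjusted p = 0.284, mt-Co1 at 0.23). Of 10 reference genes 3 rose and 0 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.204). Of 6 CD4 and regulatory T cell markers only Ctla4 was measured, at 2.05 on the deposited scale (adjusted p = 0.0277), and of 8 natural killer cell markers only Gzma, at -0.01 on the deposited scale (adjusted p = 0.989). Of 10 erythroid and platelet markers 0 were measured.

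**Figure D1:**
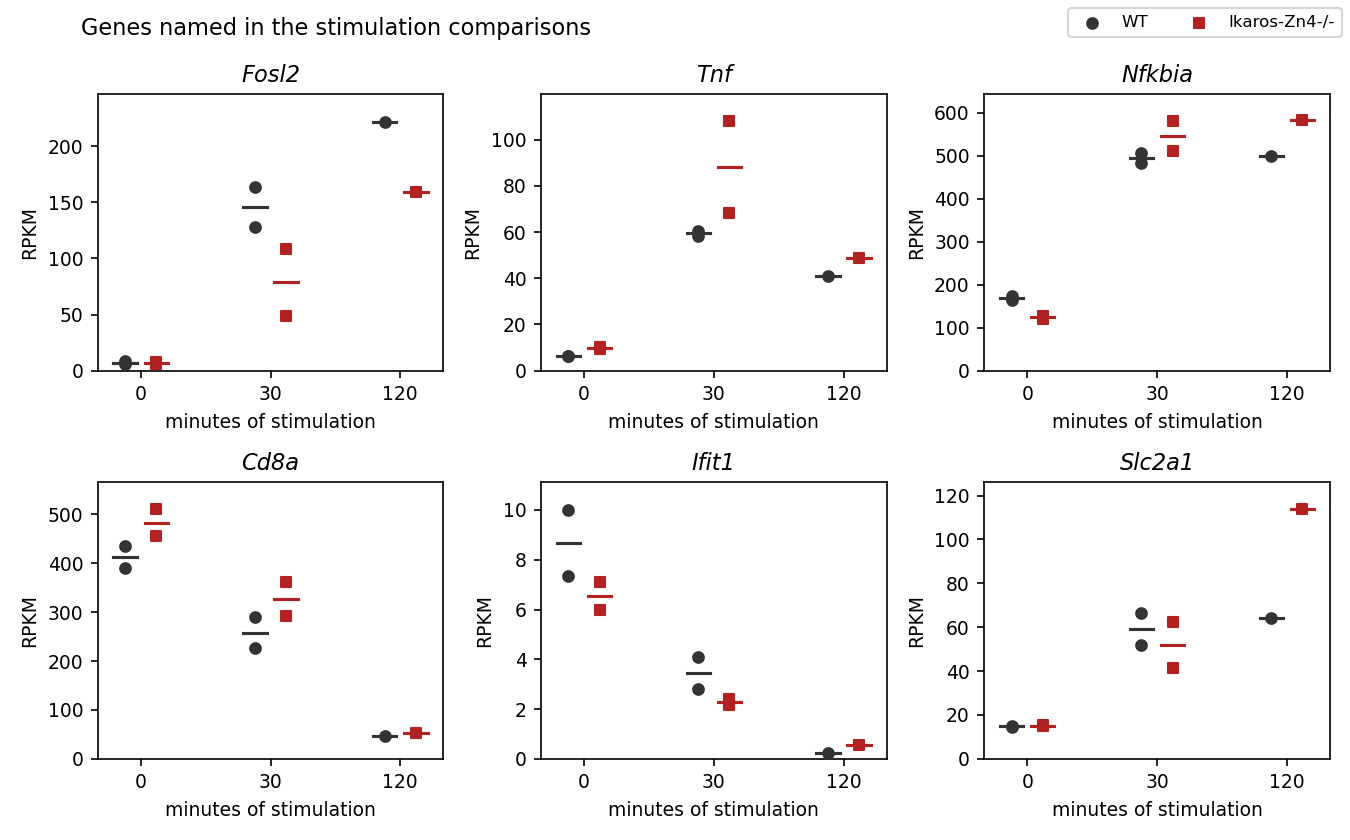
RPKM of 6 genes against minutes of stimulation (0, 30 and 120), with a point per library (circles for WT, squares for Ikaros-Zn4-/-) and a bar at each group mean. Fosl2, Tnf, Nfkbia and Slc2a1 lie higher at 30 min than at 0 min in every library of both genotypes, and Cd8a and Ifit1 lie lower, with Cd8a at 47.5 and 52.2 RPKM at 120 min.

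Over both genotypes 2317 of 12203 genes were called at 30 min, 794 higher and 1523 lower (limma, adjusted p below 0.05), with 288 rises and 111 falls of at least 2-fold. The direction of the small changes rests on the scaling, since 1124 were higher and 838 lower after scaling by the median ratio and 1025 and 1027 after quantile normalization. The count was 1183 without WT 0 min replicate 1, 779 without WT 0 min replicate 2, 872 and 1153 without WT 30 min replicates 1 and 2, 1378 and 1105 without Zn4 0 min replicates 1 and 2, and 1262 without Zn4 30 min replicate 1.

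In each genotype alone the 30 min response was compared between sets of libraries that share none. The spread of each gene, however, came from the same fit of all libraries, so the calls of the genotypes are not independent. In WT cells Fosl2 rose by 4.33 (SE 0.37, adjusted p = 0.00559), Errfi1 by 3.33 (SE 0.21, adjusted p = 0.00214) and Tnf by 3.18 (SE 0.21, adjusted p = 0.00214). In Ikaros-Zn4-/- cells Errfi1 rose by 3.43 (SE 0.21, adjusted p = 0.00196), Sertad1, a cell cycle regulator, by 3.42 (SE 0.15, adjusted p = 0.00053) and Gadd45b by 3.32 (SE 0.22, adjusted p = 0.0025). Immediate early genes rose for 8 of 28 members in WT (14 adjusted over the list alone) and for 14 in mutant cells (23 adjusted over the list alone), and 0 fell in either. Their camera adjusted p = 7.21e-13 in WT became adjusted p = 0.244 with an estimated correlation, and 2.03e-25 in mutant cells became adjusted p = 0.111 with an estimated correlation. In all 736 genes were called in WT (392 higher, 344 lower) and 334 in mutant cells (205 higher, 129 lower). Of these 169 were higher in both, where 6.59 are expected of independent lists, and 82 were lower in both, where 3.64 are expected. In opposite directions 0 were called. A shared spread favours the same genes in both lists, so these expected numbers may be too low. With the spread of the compared groups only, mutant cells had 0 calls, so the overlap could not be checked that way.

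The number called per genotype at 30 min rested on every library of the groups compared. For WT it was 105 and 17 without WT 0 min replicates 1 and 2, and 25 and 13 without WT 30 min replicates 1 and 2. For mutant cells it was 52 and 42 without Zn4 0 min replicates 1 and 2, 39 and 79 without Zn4 30 min replicates 1 and 2, 164 and 165 without WT 0 min replicates 1 and 2, and 87 and 78 without WT 30 min replicates 1 and 2. The higher and lower calls became 630 and 256 in WT and 253 and 79 in mutant cells after scaling by the median ratio. Which direction held more calls also rested on the fit, with 794 higher and 1077 lower in WT and 427 and 687 in mutant cells by limma-voom on recovered reads. In WT they were 513 and 610 with gene models of at least 300 bases and 453 and 489 with a filter at a mean of 2 RPKM, and in mutant cells 290 and 275, and 230 and 170. With the spread taken from the compared groups only, 233 were called in WT and 0 in mutant cells (2129 at an unadjusted p below 0.05, and 1114 with limma-voom on recovered reads).

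By 120 min, in 2 libraries against 4, the response was broader and included large falls. Nr4a3, an orphan nuclear receptor induced by TCR signalling (chromosome 4, 48045153 to 48086447), had 2.64 ± 0.328 RPKM at 0 min in WT cells (SD, n = 2) and 130 RPKM at 120 min, and 2.96 ± 0.738 and 167 RPKM in mutant cells. Cd8a, the coreceptor chain by which these cells are defined (chromosome 6, 71373427 to 71379173), went from 413 ± 33.1 to 47.5 RPKM in WT and from 483 ± 38.6 to 52.2 RPKM in mutant cells. Relative to the median of all genes, Nr4a3 rose by 5.61 on the log2 scale (SE 0.33, adjusted p = 4.33e-05), Fosl2 by 4.90 (SE 0.32, adjusted p = 5.95e-05), the cell cycle inhibitor Cdkn1a by 4.38 (SE 0.22, adjusted p = 3.7e-05), the cAMP-responsive factor Crem by 4.26 (SE 0.24, adjusted p = 4.23e-05) and Tnfsf11 by 3.88 (SE 0.32, adjusted p = 0.000119). Art2b fell by 4.05 (SE 0.24, adjusted p = 3.7e-05), the tetraspanin Tspan32 by 3.47 (SE 0.12, adjusted p = 3.23e-05) and Dapl1 by 3.42 (SE 0.26, adjusted p = 5.93e-05).

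Genes of the type I interferon response fell together at 120 min, 20 of 24 falling and 1 rising (the same numbers adjusted over the list alone). The antiviral genes Oas3 at -2.78 (SE 0.17, adjusted p = 3.7e-05), Zbp1 at -2.38 (SE 0.10, adjusted p = 3.23e-05) and Ifit1 at -2.28 (SE 0.18, adjusted p = 5.95e-05) were among them. Camera gave this list an adjusted p = 0.000114, and adjusted p = 0.45 with an estimated correlation. Of 22 TCR proximal signalling genes 14 fell and 3 rose (the same numbers adjusted over the list alone). Among them were Cd8a at -2.82, the TCR subunits Cd3g at -2.37 and Cd3e at -2.24 and the phospholipase Plcg1 at -1.39, though as a list they were not called (camera adjusted p = 0.0717, fry adjusted p = 0.000738). Of 23 negative regulators 13 fell and 4 rose (14 and 4 adjusted over the list alone, camera adjusted p = 0.328), the adaptor Dok2 at -1.97 and the surface receptor Cd6 at -1.41 against the ubiquitin ligase Cblb at 2.09. Of 18 effector and memory genes 9 fell and 3 rose (10 and 3 adjusted over the list alone, camera adjusted p = 0.264). These include the cytotoxic granule genes Nkg7 at -2.92 and Prf1 at -2.79.

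Immediate early genes were higher for 17 of 28 members and lower for 4 (the same numbers adjusted over the list alone). Examples were Egr2 at 3.26 and Gadd45b at 3.15. For the list, camera gave adjusted p = 4.2e-05 and adjusted p = 0.45 with an estimated correlation. NF-kB genes rose for 13 of 16 members and fell for 2 (the same numbers adjusted over the list alone). Among them were Nfkbid at 2.76, the adhesion molecule Icam1 at 2.60 and Nfkbia at 2.21. The camera adjusted p = 2.33e-05 for the list became adjusted p = 0.172 with an estimated correlation. MAP kinase feedback regulators rose for 5 of 12 and fell for 0 (the same numbers adjusted over the list alone). These include Dusp16 at 2.59 and Spred2 at 2.23. As a list they had camera adjusted p = 0.00228 and adjusted p = 0.172 with an estimated correlation. Activation transcription factors rose for 10 of 17 and fell for 3 (the same numbers adjusted over the list alone). Stat5a, a transducer of cytokine signals, rose by 3.05. Camera gave this list an adjusted p = 0.00223, and adjusted p = 0.404 with an estimated correlation. Glycolysis and nutrient transport genes rose for 8 of 16 and fell for 2 (the same numbers adjusted over the list alone). Among them were Slc38a2 at 3.52, Slc2a1 at 2.75 and Slc7a5, an amino acid transporter chain, at 2.52. For the list, camera gave adjusted p = 0.00161 and adjusted p = 0.172 with an estimated correlation. Ribosome biogenesis genes rose for 12 of 24 and fell for 4 (the same numbers adjusted over the list alone). These include Odc1, an enzyme of polyamine synthesis, at 2.40 and Nop56 at 1.43. The camera adjusted p = 0.0141 for the list became adjusted p = 0.45 with an estimated correlation.

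Cytokine and chemokine genes rose for 7 of 14 and fell for 3 (the same numbers adjusted over the list alone). Examples were Tnf at 2.67, the chemokine Ccl4 at 2.38 (3.67 in mutant cells alone, so lower in WT cells) and Tnfsf8 at -2.17. Their camera adjusted p = 0.0485 became adjusted p = 0.45 with an estimated correlation, 0.0808 with a pseudocount of 0.1 and 0.0855 after quantile normalization. Activation surface receptors rose for 7 of 15 and fell for 3 (the same numbers adjusted over the list alone). Among them were Tfrc at 1.60 and Icos at 1.30. Their camera adjusted p = 0.0292 became adjusted p = 0.322 with an estimated correlation and 0.0502 after quantile normalization. In each list called at 30 or 120 min over both genotypes, the median, the mean and the test had the same sign.

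The remaining lists were not called at 120 min, and the all-gene counts and those adjusted over the list alone were equal except where both are given. Naive and quiescence genes were 6 of 20 up and 8 down (camera adjusted p = 0.654), but 11 up and 7 down after scaling by the median ratio, with Dapl1 at -3.42 and the chromatin organiser Satb1 at 1.59. The median of that list was -0.01 and its mean -0.44, while the test pointed upward. Notch pathway genes were 5 of 8 up and 2 down (camera adjusted p = 0.0815), with the receptor Notch2 at 1.19 and the regulator Dtx1 at -2.79. Heat shock genes were 3 of 13 up and 3 down, and 4 up and 2 down under both other scalings (camera adjusted p = 0.441), with Hspa5 at 2.10 and the inducible chaperone Hspa1b at -3.22. Proliferation genes were 6 of 17 up and 6 down, and 8 up and 3 down after scaling by the median ratio (camera adjusted p = 0.288), with the replication helicase subunits Mcm7 at 1.56 and Mcm3 at 1.43 and the kinase Cdk4 at -1.26. Apoptosis regulators were 3 of 13 up and 4 down, and 4 up and 3 down under both other scalings (camera adjusted p = 0.654), with the survival gene Bcl2 at -1.40. Chromatin remodelling genes were 6 of 17 up and 6 down, and 9 up and 5 down after scaling by the median ratio (camera adjusted p = 0.425), with Chd4, the helicase of the NuRD complex that binds Ikaros, at 1.88 and the NuRD subunit Mta1 at -0.91.

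In the Ikaros family at 120 min, Ikzf2 (Helios) rose by 1.57 and Ikzf3 (Aiolos) fell by 1.18, 2 of 5 members rising and 1 falling (3 and 1 adjusted over the list alone, camera adjusted p = 0.264), while Ikzf1 had a value of 0.35 relative to the median of all genes (adjusted p = 0.795). B cell markers were 2 of 5 up and 3 down (2 and 3 adjusted over the list alone, camera adjusted p = 0.889). These include the B cell receptor chain Cd79a at 2.58 and the immunoglobulin chain Ighm at -2.35. Of 3 myeloid markers 0 rose and 1 fell (camera adjusted p = 0.517), Cst3 at -0.97. Of 10 reference genes 3 rose and 3 fell, and 4 and 2 under both other scalings (camera adjusted p = 0.664), with the succinate dehydrogenase gene Sdha at -1.38. Of 7 mitochondrial mRNAs 0 rose and 0 fell (camera adjusted p = 0.391), but 2 rose after scaling by the median ratio. On the deposited scale Ctla4 was at 0.27 (adjusted p = 0.715) and Gzma at -0.60 (adjusted p = 0.244).

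Over both genotypes 7291 genes were called at 120 min, 2356 higher and 4935 lower, with 1028 rises and 2730 falls of at least 2-fold (limma). After scaling by the median ratio the calls were 3660 higher and 3655 lower, and after quantile normalization 3411 higher and 3504 lower, so neither of these scalings gave the excess of falls seen on the deposited scale. Per genotype 5326 were called in WT (1731 higher, 3595 lower) and 5771 in mutant cells (1796 higher, 3975 lower), and after scaling by the median ratio 2821 against 2655 and 2942 against 2790. From libraries that the genotypes do not share, 1408 genes were higher in both, where 255 are expected of independent lists. In both, 3079 were lower, where 1171 are expected, while 2 and 4 were called in opposite directions. Here too the spread of each gene came from the same fit, so these expected numbers may be too low. Immediate early genes rose for 11 of 28 members and fell for 4 in WT, and rose for 17 and fell for 1 in mutant cells. Interferon genes fell for 19 of 24 in WT (camera adjusted p = 1.1e-05; adjusted p = 0.39 with an estimated correlation) and for 18 in mutant cells (0.000491; adjusted p = 0.354 with an estimated correlation). With the spread taken from the compared groups only, 2976 genes were called in mutant cells.

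How the mutation alters expression was examined over all times, 5 libraries against 5 with time in the model. Among the large differences were genes with low levels in WT cells. Nrp1, a coreceptor for semaphorins and vascular growth factor (chromosome 8, 128358604 to 128503363), had 0.336 ± 0.0479 RPKM in WT and 25.1 ± 4.36 RPKM in mutant cells (SD, n = 5 libraries over the 3 times). Gzmm, a granzyme of cytotoxic granules (chromosome 10, 79689020 to 79695261), had 1.70 ± 1.29 and 57.2 ± 17.1 RPKM. Cxcr3, a chemokine receptor of effector and memory T cells (chromosome X, 101731535 to 101734269), had 2.22 ± 1.49 and 31.4 ± 17.8 RPKM. In the other direction, Fam46a, a noncanonical poly(A) polymerase (chromosome 9, 85320439 to 85327348), had 8.98 ± 3.01 RPKM in WT and 0.379 ± 0.223 RPKM in mutant cells.

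Differences between the genotypes are log2 values of Ikaros-Zn4-/- minus WT on the deposited scale, where the median of all genes was 0.01. The membrane protein gene Tmem176b was higher by 5.17 (SE 0.29, adjusted p = 6.9e-06) and Tmem176a by 4.58 (SE 0.19, adjusted p = 9.68e-07), though these neighbours overlap on opposite strands of chromosome 6 (48833818 to 48841496 and 48840919 to 48847071) and may share reads. Gzmm was higher by 4.50 (SE 0.28, adjusted p = 1.43e-05), Pdlim4, a cytoskeletal protein, by 4.45 (SE 0.22, adjusted p = 3.16e-06), Nrp1 by 4.27 (SE 0.11, adjusted p = 1.21e-07), the prohormone convertase Pcsk1 by 4.22 (SE 0.18, adjusted p = 1.34e-06) and the membrane metalloprotease Mmp14 by 4.16 (SE 0.16, adjusted p = 8.41e-07). Fam46a was at -2.81 (SE 0.16, adjusted p = 6.69e-06), H2-Ob, a chain of a modulator of MHC class II peptide loading, at -2.36 (SE 0.21, adjusted p = 0.000142), the receptor Gpr174 at -1.84 (SE 0.10, adjusted p = 5.1e-06) and Crlf3 at -1.75 (SE 0.21, adjusted p = 0.000843). Nrp1, Gzmm and Fam46a separated all mutant from all WT libraries at every time, which was not checked for each of the other genes.

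Effector and memory genes were higher for 10 of 18 members and lower for 0 (the same numbers adjusted over the list alone). Besides Gzmm these include Cxcr3 at 3.27 (SE 0.12, adjusted p = 8.41e-07), the interleukin 18 receptor Il18r1 at 2.85 (SE 0.12, adjusted p = 1.34e-06) and the T-box transcription factor Eomes at 1.64 (SE 0.12, adjusted p = 3.72e-05). The call of this list held under both correlations, with camera adjusted p = 7.86e-09 and adjusted p = 0.0153 with an estimated correlation. The Ikaros family was higher for 4 of 5 members (the same number adjusted over the list alone). The differences were Ikzf2 at 1.19, Ikzf3 at 1.12, Ikzf4 (Eos) at 1.05 and Ikzf1 at 0.59, while Ikzf5 (Pegasus) had a value of -0.02 (adjusted p = 0.907). The family had a camera adjusted p = 3.64e-05 and adjusted p = 0.0683 with an estimated correlation. Ikzf3 (chromosome 11, 98464902 to 98546031) had 23.2 ± 7.87 RPKM in WT and 52.0 ± 18.2 RPKM in mutant cells (SD, n = 5).

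Activation transcription factors were higher for 5 of 17 and lower for 0 (7 and 2 adjusted over the list alone). Among them were Eomes, given above, and the T-box factor Tbx21 at 1.47. Camera gave this list an adjusted p = 0.0412, and adjusted p = 0.462 with an estimated correlation. Cytokine genes were higher for 3 of 14 and lower for 0 (5 and 0 adjusted over the list alone). Tnfsf11 was among these at 2.37. For the list, camera gave adjusted p = 0.00444 and adjusted p = 0.156 with an estimated correlation. Ribosome biogenesis genes were higher for 4 of 24 and lower for 0 (8 and 0 adjusted over the list alone). The nucleolar methyltransferase Nop2 was at 0.53. The camera adjusted p = 0.000443 for the list became adjusted p = 0.418 with an estimated correlation. Glycolysis and nutrient transport genes were higher for 4 of 16 and lower for 0 (5 and 0 adjusted over the list alone). The glycolytic enzyme Eno1 was at 0.73. As a list they had camera adjusted p = 0.0327 and adjusted p = 0.195 with an estimated correlation. Of 28 immediate early genes 0 passed in either direction (also 0 adjusted over the list alone), but as a list they were shifted downward, with Fos at -0.93 (adjusted p = 0.199) and Junb at -0.54 (adjusted p = 0.484). That shift had a camera adjusted p = 0.00238, adjusted p = 0.673 with an estimated correlation and 0.27 with fry.

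Interferon genes were divided, 5 of 24 higher and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.0501). These include Oas2 at 1.20 and Oasl2 at 1.17 against Oasl1 at -1.52. Of 5 B cell markers 2 were higher and 2 lower (the same numbers adjusted over the list alone, camera adjusted p = 0.54). Cd74, the MHC class II invariant chain, was at 3.36 and the immunoglobulin light chain Igkc at 2.55, against Cd79b at -0.83 and Ighm at -0.56 (adjusted p = 0.0161). The Igkc difference was present at 0 min (2.875) and 30 min (3.496) only, and at 120 min Igkc is listed at 0 in both libraries, while Cd74 had 3.04 RPKM in the WT and 41.4 RPKM in the mutant library. The Ighm call was lost without the WT (0.0583) or the Zn4 (0.0591) 120 min library, and without both (0.062). Of 3 myeloid markers 1 was higher, the integrin Itgam at 0.90 (1 adjusted over the list alone, camera adjusted p = 0.192). The natural killer cell marker Gzma, which effector CD8+ T cells also express and the effector and memory list also holds, was at 2.26 (adjusted p = 0.00104) and Ctla4 at 0.33 (adjusted p = 0.681).

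Activation surface receptors were higher for 4 of 15 and lower for 0 (4 and 1 adjusted over the list alone, camera adjusted p = 0.495). Examples were the inhibitory receptors Lag3 at 1.35 and Pdcd1 at 1.09. TCR proximal genes were higher for 4 of 22 and lower for 0 (5 and 1 adjusted over the list alone, camera adjusted p = 0.192). The adaptor Lat was at 0.59. Negative regulators were 3 of 23 higher and 3 lower (the same numbers adjusted over the list alone, camera adjusted p = 0.575), the cytokine signalling suppressors Socs3 at 1.21 and Cish at 0.89 against Cd6 at -0.46. Of 12 MAP kinase feedback regulators only Spry2, at 3.22, passed (1 adjusted over the list alone, camera adjusted p = 0.192). Apoptosis regulators were 2 of 13 higher and 1 lower (the same numbers adjusted over the list alone, camera adjusted p = 0.377). These include Pmaip1 at 2.26 and the death receptor Fas at -0.77. Notch pathway genes were 2 of 8 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.495). Examples were the DNA-binding partner Rbpj at 0.48 and Notch2 at -0.46.

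In the NF-kB list 1 of 16 genes was called between the genotypes (1 adjusted over the list alone, camera adjusted p = 0.981), in the proliferation list 1 of 17 (0 adjusted over the list alone, camera adjusted p = 0.456), in the chromatin list 1 of 17 (1 adjusted over the list alone, camera adjusted p = 0.501), and in the naive and quiescence list 1 of 20 was higher and 1 lower (the same numbers adjusted over the list alone, camera adjusted p = 0.495). These 5 genes, Tnip1, Cdk4, Mta3, Dapl1 and Foxp1, each lost the call in at least 4 of the fits without a library. No heat shock gene passed (camera adjusted p = 0.0501, Hspa5 at 0.14), no reference gene (camera adjusted p = 0.575, B2m at 0.24) and no mitochondrial mRNA (camera adjusted p = 0.552, mt-Co1 at -0.03), and adjusted over the list alone the number was 0 for each.

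**Figure D2:**
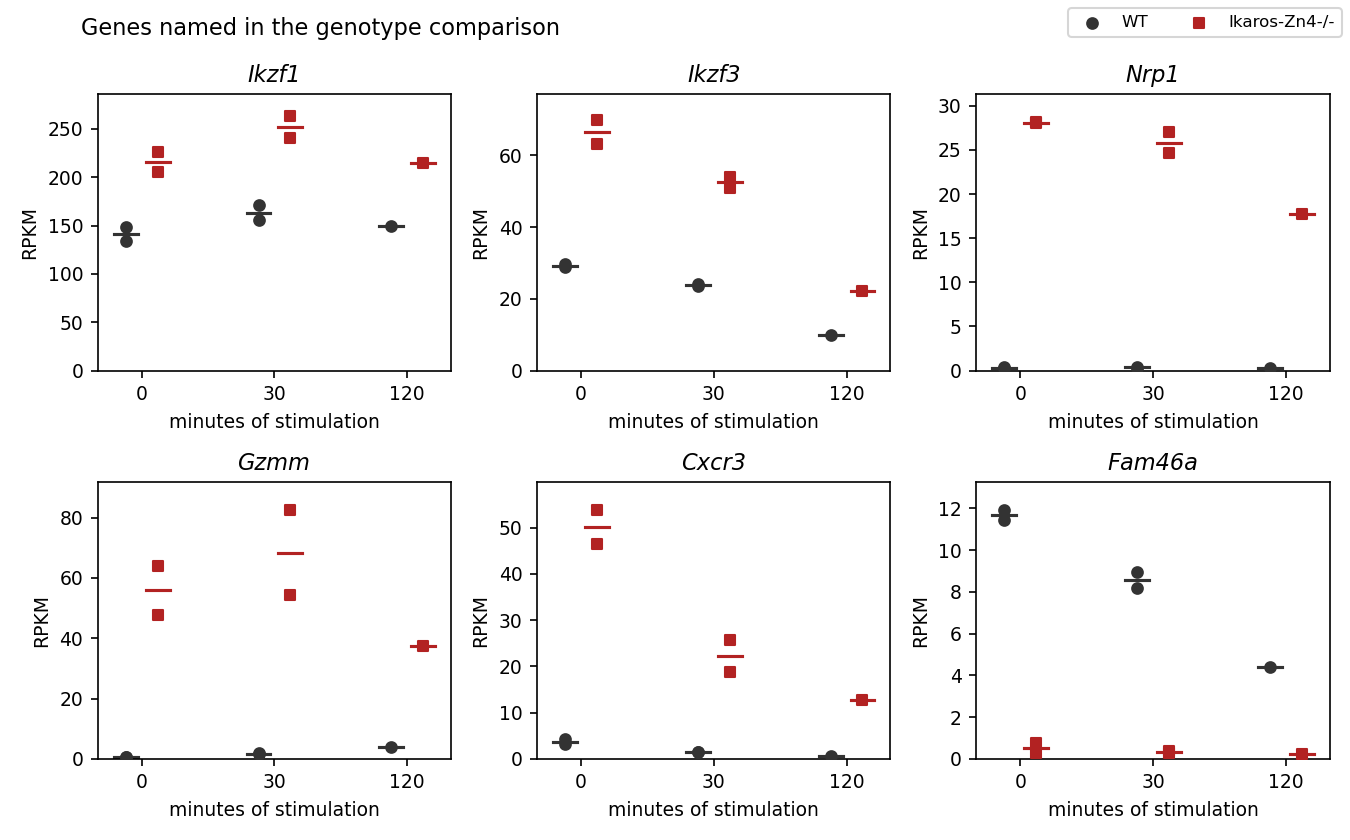
RPKM of 6 genes against minutes of stimulation (0, 30 and 120) in WT (circles) and Ikaros-Zn4-/- (squares) cells, with a point per library and a bar at each group mean. Ikzf1, Ikzf3, Nrp1, Gzmm and Cxcr3 lie higher and Fam46a lower in mutant than in WT libraries at every time, with Nrp1 between 17.7 and 28.2 RPKM in mutant and below 0.40 RPKM in WT libraries.

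Over all times 1150 of 12203 genes were called between the genotypes, 755 higher and 395 lower in mutant cells, with 240 and 57 by at least 2-fold (limma). The count was 756 without WT 0 min replicate 1 and 706 without WT 30 min replicate 1. With only the libraries numbered 1 it was 82 and with only those numbered 2 it was 117. The title of the Ikaros-Zn4-/- 120 min sample numbers it 1 and its description 2, which was used, and with that library as number 1 the counts were 82 and 0 (limma, 1689 at an unadjusted p below 0.05 for the latter). Of 73 named genes called here, 51 and 50 lost the call in these smaller fits, Ikzf1 among them (adjusted p = 0.19 and 0.0771), as did 75 and 72 of the 90 named genes called at 30 min over both genotypes. With that library as number 1, these losses were 51 and 73 of the 73 and 90 of the 90 in both fits.

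**Figure D3:**
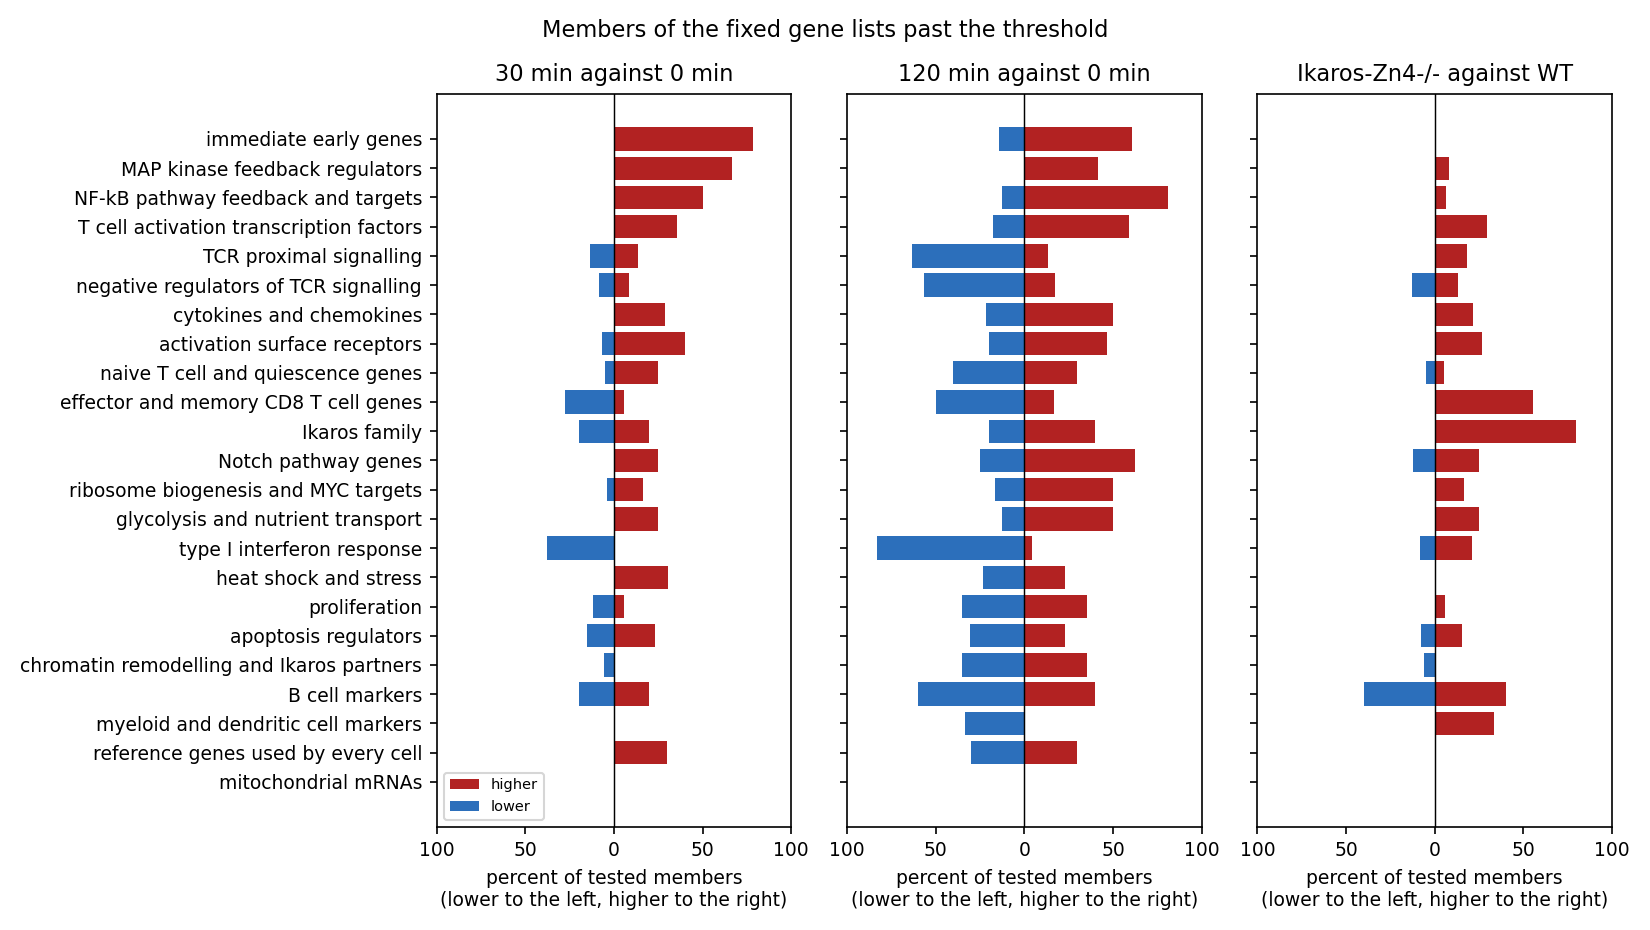
Percent of the tested members of each gene list that were called higher (to the right) or lower (to the left) at 30 min, at 120 min and between the genotypes over all times, on the deposited scale. Long bars include immediate early genes at 30 min (22 of 28 higher) and, at 120 min, interferon genes (20 of 24 lower) and NF-kB genes (mostly higher). Between the genotypes the Ikaros family, which has few members, has a longer bar than effector and memory genes (10 of 18 higher). At 120 min the naive and quiescence list turns from 6 higher and 8 lower to 11 and 7 after scaling by the median ratio, and the apoptosis list from 3 and 4 to 4 and 3.

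The genotype difference was already present in unstimulated cells. At 0 min Tmem176b was higher by 5.62 (adjusted p = 5.45e-05), Gzmm by 5.06 (adjusted p = 0.000215) and Nrp1 by 4.47 (adjusted p = 5.45e-05), and Fam46a was at -3.08 (adjusted p = 0.000492) and H2-Ob at -2.70 (adjusted p = 0.00167). At 30 min Tmem176b was higher by 5.56 (adjusted p = 5.87e-05) and Nrp1 by 4.30 (adjusted p = 5.87e-05), and Fam46a was at -2.85 (adjusted p = 0.000756). Effector and memory genes were higher for 7 of 18 at 0 min (10 adjusted over the list alone; camera adjusted p = 1.81e-09; adjusted p = 0.0865 with an estimated correlation) and for 6 at 30 min (10 adjusted over the list alone; 9.57e-07; adjusted p = 0.16 with an estimated correlation). Among immediate early genes 0 of 28 passed at 0 min, but 6 were lower adjusted over the list alone and the list was shifted downward (camera adjusted p = 2.62e-08; adjusted p = 0.503 with an estimated correlation, 0.129 with fry), as were heat shock genes (0.00188; adjusted p = 0.543 with an estimated correlation). The median of immediate early genes at 0 min was -1.04 and -1.24 for the mutant libraries against WT replicate 1, and -0.282 and -0.305 against WT replicate 2.

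At 0 min 302 genes were called between the genotypes (234 higher, 68 lower) and at 30 min 319 (245 higher, 74 lower). From libraries that these contrasts do not share, 177 were higher at both times, where 4.70 are expected of independent lists. At both times 38 were lower, where 0.412 are expected, with 0 in opposite directions. These contrasts also share the spread of each gene, so the expected numbers may be too low. The count at 0 min was 108 and 105 without WT 0 min replicates 1 and 2, 149 and 118 without Zn4 0 min replicates 1 and 2, 194 and 193 without WT 30 min replicates 1 and 2, and 96 with the spread of the compared groups only. The count at 30 min was 99 and 86 without WT 30 min replicates 1 and 2, 113 without Zn4 30 min replicate 2, 188 and 185 without WT 0 min replicates 1 and 2, and 80 with the spread of the compared groups only.

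At 120 min each genotype had 1 library, so the difference has no replicate check. Pcsk1 had 1.26 RPKM in the WT and 37.0 RPKM in the mutant library, Spry2 0.228 and 14.9 RPKM, and Pmaip1 2.41 and 41.4 RPKM. In the other direction Crlf3 differed by -2.83 on the log2 scale. Of the genes called at 0 min, 225 of the 234 higher ones were higher in the mutant library at 120 min (96.2%, against 48.8% of all genes) and 60 of the 68 lower ones were lower (88.2%, against 49.8%). The median log2 difference of effector and memory genes was 1.15 at percentile 100 of 10000 random lists matched on expression, that of the Ikaros family 0.95 at percentile 99.98, that of ribosome biogenesis genes 0.45 at percentile 100 and that of interferon genes 0.42 at percentile 100. Activation transcription factors, cytokines, MAP kinase feedback regulators, glycolysis and nutrient transport genes and heat shock genes lay at percentiles 99.56 to 99.95. Immediate early genes had a median of -0.04 at percentile 26.5. These percentiles describe the 2 libraries and not the genotypes. Among 8510 genes with a mean of at least 2 RPKM, 280 were at least 2-fold higher and 131 at least 2-fold lower in the mutant library.

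Whether the mutation changed the response to stimulation itself was tested as the difference between the genotypes' responses. The largest differences at 30 min among genes called in either genotype were Id3, an inhibitor of E proteins, at 2.18 and the AP-1 subunit Junb at 2.09, positive where the mutant response was the higher, and the phosphatase Dusp10 at -1.51 (adjusted p = 0.876 each). Id3 had 37.5 ± 8.36 and 34.3 ± 10.5 RPKM in WT cells at 0 and 30 min and 12.6 ± 5.26 and 53.1 ± 5.31 RPKM in mutant cells (SD, n = 2). Dusp10 had 27.6 ± 0.793 and 182 ± 8.12 RPKM in WT and 47.1 ± 2.38 and 108 ± 23.9 RPKM in mutant cells. At 120 min Hspa1b was at 3.33 (adjusted p = 0.963) and the antiviral membrane protein Bst2 at 1.36 (adjusted p = 0.703). Limma called 0 genes at 30 min (656 at an unadjusted p below 0.05, smallest adjusted p = 0.876) and 0 at 120 min (661, smallest adjusted p = 0.197), and limma-voom on recovered reads also called 0 at each time. As a list immediate early genes had a median difference of 0.53 at 30 min (camera adjusted p = 4.04e-05; adjusted p = 0.997 with an estimated correlation) and 0.75 at 120 min (8.77e-07; adjusted p = 0.495 with an estimated correlation). Leaving out WT 0 min replicate 2 gave 1 call at 30 min, the microRNA Mir6946 at -5.67 (adjusted p = 0.0393).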

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

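Of the tests in this part, the trend with transcript length and the other splits of the libraries were set out beforehand, and the tests of the WT 0 min library, handling stress, scaling and the genes that gained most reads were chosen only after the result was seen.

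The results given here are gene lists whose response to stimulation differed between the genotypes by a test of the difference itself (camera on the interaction), although no single gene passed and each call was lost with an estimated correlation. At 30 min the median difference of immediate early genes, mutant minus WT response, was 0.53 on the log2 scale (camera adjusted p = 4.04e-05; adjusted p = 0.997 with an estimated correlation). At 30 min activation surface receptors had a median difference of -0.35 (camera adjusted p = 0.00244; adjusted p = 0.424 with an estimated correlation). At 120 min immediate early genes had a median difference of 0.75 (8.77e-07; adjusted p = 0.495 with an estimated correlation) and heat shock genes of 0.87 (3.59e-07; adjusted p = 0.46 with an estimated correlation). MAP kinase feedback regulators had 0.51 (0.0402; adjusted p = 0.451 with an estimated correlation) and cytokines 0.30 (0.0389; adjusted p = 0.495 with an estimated correlation). Ribosome biogenesis genes had 0.32 (0.000287; adjusted p = 0.451 with an estimated correlation) and glycolysis and nutrient transport genes 0.19 (0.0402; adjusted p = 0.451 with an estimated correlation). Interferon genes had 0.31 (0.00324; adjusted p = 0.574 with an estimated correlation). The 120 min values rest on 1 library per genotype. No group has enough samples for a test of single samples that stand apart.

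The differences of immediate early genes, and part of those of heat shock genes, go with lower starting levels in mutant cells at 0 min, where the medians of immediate early genes over the 4 pairings of a mutant with a WT library were -1.04, -0.282, -1.24 and -0.305. WT 0 min replicate 1 has the higher levels, and without it the mean of the medians was -0.293. That exceeds in size the gap between the mutant libraries (-0.282 against -0.305), so the condition set for an effect of that library alone was not met. It is smaller than the largest replicate gap, but that gap is between the WT libraries and rests on replicate 1 itself. An effect of that library alone and a genotype effect thus cannot be told apart with 2 libraries per group. Heat shock genes were lower in every pairing (-0.716, -0.311, -0.78 and -0.321), with the smallest distance below the median of all genes at -0.279, so handling that stressed the WT cells more during sorting is a candidate explanation for the lower start. It does not cover the whole difference of heat shock genes at 120 min, since 12 of the 13 were then higher in the mutant library, with a median of 0.40 against -0.41 at 0 min, and the cause of that part was not tested. A weaker basal expression in Ikaros-Zn4-/- cells, the biological alternative the design offers, stays open and untested.

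Falls outnumber rises at 120 min on the deposited scale by 4935 to 2356. After a trend with transcript length was removed from each library, rises made up 30.3% of the calls, against 32.3% before (2213 rises and 5099 falls). The removal kept the overall level of each library (median change -0.355), so it cannot show whether a length trend lowered that level. It shows only that falls still outnumbered rises once changes no longer went with length. A few genes that took more of the reads are not the whole cause. Over the 4 pairings of a 120 min with a 0 min library of its genotype, the 10 genes that gained most took 2.21% to 2.78% more of the reads. That lowers the other genes by at most 0.041 on the log2 scale (-0.041), against median changes of -0.245 to -0.355, and rises made up 33.7% of the calls with such genes left out of the totals (2451 rises and 4827 falls). After scaling by the median ratio rises made up 50% of the calls, but that scaling centres the genes, so a general fall of mRNA relative to the induced genes and an effect of the authors' scaling cannot be told apart. Whether stimulation lowers many transcripts relative to the rest is thus open.

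Other splits of the libraries called fewer genes than the real groups. Of the 35 splits of the 8 libraries at 0 and 30 min into equal sets, 1, the real split, called as many as 1869 genes, and the highest other split, which parts the genotypes, called 405. For the genotype over all times 1 of 100 drawn splits reached 1150, the highest other being 7, and 1 of the 36 splits balanced over the times, the highest other being 0. The real split is itself counted, so the share could not fall below 1 of 35, 1 of 100 and 1 of 36. The other splits also leave the real difference in the spread, which lowers their counts. The real groups called the most genes in each set, but chance assignment of the libraries is not excluded.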

How the results depend on the processing

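The fits with limma-voom on reads recovered from the RPKM steps, with gene models of at least 300 bases only, with libraries numbered 1 or 2 only, without the 120 min libraries and with the Zn4 120 min library as number 1 were chosen after seeing the data. Of 645 called results for named genes none reversed, 298 stayed called under every setting that was run for them and 347 lost the call in at least 1. Not every setting applies to every result, and the fits by library number cover 163 of them, the fit without the 120 min libraries 354 and that of the compared groups only 572. The cause was not tested for the changes below unless fewer libraries or genes entered the fit. With the spread from the compared groups only, which leaves fewer degrees of freedom, 233 genes were called at 30 min in WT, 0 at 30 min and 2976 at 120 min in mutant cells, and 96 at 0 min and 80 at 30 min between the genotypes. With limma-voom the counts were 1871 and 1114 for 30 min in WT and mutant cells, and 672 and 655 for the genotypes at 0 and 30 min. With gene models of at least 300 bases, 1123 and 565 were called at 30 min in WT and mutant cells. Libraries numbered 1 only gave 67 calls for 30 min over both genotypes and 82 for the genotype over all times, and those numbered 2 only gave 66 and 117. With the Zn4 120 min library as number 1, as its title has it, limma gave 0 and 82 calls for those numbered 1 and 0 and 0 for those numbered 2. For the counts of 0 the smallest adjusted p was 0.0502, 0.138 and 0.126, with 3547, 2147 and 1689 genes at an unadjusted p below 0.05. The interaction at 120 min had 1 call with a pseudocount of 0.1 (Gm24366), 13 without a filter and 3 with moderation without the trend, microRNA, predicted and 5S ribosomal RNA models such as Gm25809 (3.52). The genotype difference at 120 min, 411 genes at least 2-fold apart without a test, had 83 calls with the pooled spread of the other groups. Of 85 list calls over all contrasts 3 held with an estimated correlation: MAP kinase feedback regulators at 30 min in mutant cells (adjusted p = 0.0439) and over both genotypes, and effector and memory genes over all times.

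Leaving out each library in turn gave 13 to 744 calls for 30 min in WT, 39 to 337 in mutant cells and 779 to 2316 over both. For 120 min the ranges were 3840 to 5346 in WT, 4615 to 5897 in mutant cells and 6606 to 7385 over both. Between the genotypes they were 105 to 300 at 0 min, 86 to 315 at 30 min and 706 to 1036 over all times (909 without both 120 min libraries), and for the interactions 0 to 1 at 30 min and 0 to 0 at 120 min. Leaving out a library also lowers the degrees of freedom. Ikzf5, never called between the genotypes, changed sign, to 0.059 without WT 0 min replicate 2, 0.005 without Zn4 0 min replicate 2 and 0.001 with limma-voom at 0 min, to 0.010 without WT 30 min replicate 2 at 30 min, and over all times to 0.021 without WT 30 min replicate 2, 0.014 without Zn4 30 min replicate 2 and 0.082 with libraries numbered 1 only, by either number of the Zn4 120 min library. Leaving out each library, Ikzf5 ranged from -0.069 to 0.059 at 0 min, -0.206 to 0.010 at 30 min and -0.052 to 0.021 over all times.

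The groups share replicate numbers, but nothing in the labels says what a number marks, and the correlations of the differences between replicates 1 and 2 for the pairs of groups were 0.23, 0.16, 0.0369, 0.2, 0.197 and 0.16. All are positive and 5 of the 6 are above 0.1, so a component that goes with the number is possible, but 1 is near 0 and the library numbered 1 is also the deeper of each pair. The recovered reads come to 94.0% to 96.5% of the depth in the 4 libraries numbered 1 and 97.4% to 101% in the others, and 346 to 413 genes against 548 to 764 are at 0. Both 120 min libraries lie with those numbered 2 in this, although their depths are near those of libraries numbered 1, so what goes with the number is shared with time at 120 min. With the block 7717 genes were called at 120 min over both genotypes (2427 higher, 5290 lower). Whether the numbers pair the samples is thus open, and the fit without the block was kept. With the replicate block 1891 genes were called at 30 min in WT (694 higher, 1197 lower), 961 in mutant cells (374 higher, 587 lower), 3484 over both and 549 between the genotypes at 30 min, and there were 78 list calls. With the Zn4 120 min library as number 1 in the block, 1759 genes were called between the genotypes over all times, against 1567 with it as number 2. The block took list calls from cytokines (0.054) and interferon genes (0.054) at 30 min over both genotypes, naive genes at 30 min (0.0667), cytokines at 120 min (0.0935), cytokines (0.0841) and naive genes (0.0686) at 30 min in WT, cytokines at 30 min in mutant cells (0.0668), activation surface receptors between the genotypes at 0 min (0.0524) and activation transcription factors between the genotypes over all times (0.055). Depth limits the precision of genes with few reads, and in the simulation of the genotype contrast at 0 min 78.8% of 4-fold but 8.96% of 2-fold and 1.49% of 1.5-fold changes were recovered.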

Other observations

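The tests of B cell RNA and of memory-phenotype cells in this part, and the genes named in the paragraph on other genes, were chosen only after the result was seen.

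Other genes were higher in Ikaros-Zn4-/- than in WT cells over all times (limma, 5 libraries against 5). Ctnnd1, which encodes p120 catenin, a cytoplasmic partner of cadherins (chromosome 2, 84600071 to 84650765), was higher by 2.07 on the log2 scale (SE 0.16, adjusted p = 4.52e-05), Ctnna1, which encodes alpha-catenin (chromosome 18, 35118859 to 35254779), by 2.00 (SE 0.11, adjusted p = 6.69e-06) and Cdh1, which encodes E-cadherin (chromosome 8, 106603351 to 106670246), by 2.10 (SE 0.20, adjusted p = 2e-04). Gucy1a3 and Gucy1b3, which encode the subunits of soluble guanylate cyclase, the nitric oxide receptor, were higher by 2.45 (SE 0.23, adjusted p = 0.000164) and 3.22 (SE 0.20, adjusted p = 1.32e-05). They are neighbours on chromosome 3 (82032006 to 82074689 and 82092427 to 82145789). The growth factor receptor genes Igf1r and Igf2r were higher by 2.39 (SE 0.09, adjusted p = 8.41e-07) and 1.02 (SE 0.07, adjusted p = 2.19e-05). No list of these genes was fixed, so they were not tested as groups.

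Genes higher in mutant cells include Cd74, at 3.36, and effector and memory genes, which other cells in the sorted fraction could bring. The B cell markers moved apart. Igkc was higher by 2.55 on the log2 scale (95% interval 1.518 to 3.58), as RNA from B cells would need, while the upper 95% bounds of Cd79a, Cd79b and Ighm lay at or below 0.515, with changes of 0.19, -0.83 and -0.56. At 120 min Igkc is listed at 0 in the library of each genotype while Cd74 had 3.04 and 41.4 RPKM, which goes against RNA from B cells as the source of Cd74 but rests on 1 library per genotype, and Ighm was also lower at 120 min in both genotypes. The sort for CD8+ cells would remove B cells, but a few may escape it, and no profile of B cells was used here to say which levels their share would need. For Cd74 and Igkc, RNA from B cells and expression in the sorted T cells thus cannot be told apart. A larger share of memory-phenotype CD8+ T cells also remains open. The abundant memory transcripts Ccl5 and Cd44 were at 0.18 and -0.31, with 95% intervals of -0.139 to 0.497 and -0.608 to -0.012. The Cd44 interval lies below 0, though Cd44 was not called (limma, adjusted p = 0.196), and the sort for low CD44 would remove such cells. The Ccl5 interval is too wide to exclude a small share that may escape the sort. This and a release of effector genes within naive cells thus cannot be told apart. The latter is the biological alternative that the design offers and was not tested.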
